A study of Mus musculus with 6 samples.

How the data were processed

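Polyadenylated RNA of 6 cultures of mouse granulocyte-monocyte progenitors with ER-HOXA9 was sequenced. The deposited table holds counts of reads per gene as the authors made them, without normalisation, and its Length column, in base pairs (another unit), was not used here. The submitters' processing notes name STAR 2.7.0f for alignment to the mm10 genome and deepTools 3.0.2, and the labels call the table featurecount. The strand setting, the handling of reads with several matches and the annotation release are not given in the sources used here, so counts of overlapping genes and of near-identical gene copies are uncertain. The table has 23337 genes, of which 8069 had 0 counts in all libraries, and 25 names look like dates, so genes behind those names were not matched. Gene positions are those given in the deposited table, on mm10, and older symbols were matched through RefSeq synonyms.

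Total counts per library ranged from 11305666 to 16948697. Replicates of 1 group varied by more than counting error, with a chi-square per degree of freedom of 14.1 for untreated cells, 5.78 for vehicle and 1.85 for the drugs. These values come from raw counts that include Rn45s. That gene took 20.45% and 24.64% of the counts in untreated replicates 1 and 2, so it carries part of the first value. Genes with low counts were removed with filterByExpr, which left 11283. Libraries were scaled with the trimmed mean of M values (TMM), and all 3 groups were fitted in 1 model with edgeR 4.0.16 under R 4.3.3, which gives 3 residual degrees of freedom and a common biological coefficient of variation of 0.0592. The 3 comparisons used the edgeR quasi-likelihood F test, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The SE of a log2 change was derived from the F statistic. Log2 changes carry the prior count of 0.125 that edgeR adds. For a gene with 0 counts in 1 group, a lower bound was computed with a floor of 3 counts over that group, and for 1 to 3 counts a ratio with its exact 95% binomial interval. Whether replicate numbers pair the cultures is not given. The correlation across genes of deviations with the same number was 0.0807 for drug and vehicle, -0.199 for vehicle and day 0 and -0.0604 for drug and day 0, so the numbers were not used in the model, and blocks for replicate number were fitted as alternatives.

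The 39 gene lists held 928 genes, of which 926 were found, 13 of them by an older symbol (Chi3l3 for Chil3, Sfpi1 for Spi1). The comparisons, tests, gene lists and alternatives were chosen before the data were examined, except where stated. Lists with at least 5 tested genes were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, which compares a list with all other genes, with Benjamini-Hochberg adjustment within each comparison. Every called list is given with a second adjusted p in which camera estimates that correlation, and none of the calls was kept by it. A larger correlation was not always the reason. In drug versus vehicle the estimate was 0.368 for secondary granule genes. It was 0.000862 for myeloid transcription factors and -0.0468 for GFI1 targets, under the preset, and their calls were lost as well. A call lost in this way is therefore not by itself evidence of correlation between the genes of a list. Counts of members adjusted over the list alone use only the genes of that list.

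Genes were named by a rule. It took the 5 largest rises and 5 largest falls per comparison among called genes whose replicates did not overlap and which averaged at least 10 CPM in the higher group, passing over predicted genes (1 in vehicle against day 0). It added up to 4 called members of each list described (the 2 with the smallest p and the 2 with the largest change) and 15 key genes. Some genes that the rule selected are not reported here. Members that moved against their list, genes near 0 and the gene families were chosen after their values were seen. Those families were tested with Fisher's exact test, two-sided, adjusted over 84 tests. It treats genes as independent, which related genes in the same libraries are not, so its p values can be too small. The correlation and covariance of comparisons were set beside 50 simulations of unchanged groups that share libraries, and neighbouring genes beside 2000 permutations of gene order.

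The tests were tried on simulated data. Counts were simulated at the depths of these libraries, with genes independent and the same fitted spread in all groups. With genes shifted, drug versus vehicle recovered 68.7% of 1.5-fold and 91% of 2-fold changes and all 66 of 4-fold. It made 7 false calls among 11083 unchanged genes. With no change simulated, 0 of 11283 genes were called in vehicle versus day 0. The real replicates differed in spread between groups, so these rates of false calls may not hold for the real comparisons. Of 10 lists with a planted shift 10 were called, and 1 of 10 without. With an estimated correlation 10 and 0 were called.

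Alternatives were DESeq2 1.42.0, limma-voom, other scaling (DESeq2 size factors, library totals), no filter or a stricter filter (at least 1 CPM), a block for replicate number, fits of only the 2 groups compared, a minimum of 1.5-fold (glmTreat), fry, lists without shared genes and leaving out each library. Fits without Rn45s, a block with vehicle numbers exchanged, the overlap with each library left out and the overlap with the 2 vehicle libraries split between the comparisons were added after the data were examined. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.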

Results

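RNA was sequenced from mouse (C57BL6) bone marrow granulocyte-monocyte progenitors that carried ER-HOXA9, an estrogen receptor fusion of the homeobox transcription factor HOXA9 that holds such cells in an immature, dividing state while beta-estradiol is present. The medium contained 0.5 µM beta-estradiol and stem cell factor. The 3 groups had 2 biological replicates each. They were untreated cells at day 0, cells kept 3 days with the solvent DMSO (vehicle), and cells kept 3 days with a combination of 3 drugs. The drugs were 200 nM GSK-LSD1, an inhibitor of the histone demethylase LSD1, 5 µM mercaptopurine, a purine antimetabolite, and 5 µM cerulenin, an inhibitor of fatty acid synthase. Total counts of replicates 1 and 2 were 16948697 and 13139172 in untreated cells, 12459793 and 11305666 with vehicle, and 12290882 and 15310378 with the drugs. Rn45s, the precursor of ribosomal RNA, took 22.5% ± 2.96 (SD, n = 2) of the counts at day 0, 15.4% ± 1.06 with vehicle and 15.8% ± 0.156 with the drugs. Levels below are normalised read counts in the usual CPM unit, which scales each library to the same effective total, given as mean ± SD with n = 2 per group, and log2 changes are given ± SE. Counting intervals and floors cover counting error only.

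The first comparison asked what the drug combination did to the progenitors relative to solvent on the same day. Genes of the neutrophil and monocyte programmes were among the largest rises. Mmp8, the collagenase of neutrophil granules, rose from 10.35 ± 3.46 to 3642 ± 223 CPM, a log2 change of 8.46 ± 0.175 (adjusted p = 3.51e-12). Gfi1b, a transcriptional repressor that recruits LSD1 to its targets, had 1 and 0 counts in the vehicle libraries and reached 87.8 ± 0.83 CPM with the drugs. Its ratio was 2160 (95% counting interval 387.4 to 85360; adjusted p = 5.5e-12). Ptgfrn, a membrane protein that binds tetraspanins, had 0 counts in both vehicle libraries and 34.8 ± 0.291 CPM with the drugs, at least 285-fold higher against a floor of 3 counts over the group (adjusted p = 2.75e-09). Ctss, the lysosomal protease cathepsin S, had 0 and 3 counts with vehicle and 37.3 ± 2.17 CPM with the drugs, a ratio of 307 (104.8 to 1491). Ms4a4c, a membrane protein of the MS4A family, had 2 and 1 counts with vehicle and 18.7 ± 0.213 CPM with the drugs, a ratio of 153 (52.1 to 744.6).

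The largest falls included Fcnb, a ficolin of the lectin complement pathway, which went from 20.5 ± 2.94 to 1.89 ± 0.0664 CPM (log2 change -3.43 ± 0.189, adjusted p = 2.92e-08). Myh7b, a myosin heavy chain gene, fell by 2.41 ± 0.119 on the log2 scale, and Tuba8, an alpha-tubulin, changed by -2.34 ± 0.11. Rtn4rl2, a receptor of the Nogo family, changed by -2.28 ± 0.207. Car2, the carbonic anhydrase also used as an erythroid marker, changed by -2.17 ± 0.0988, from 68.5 ± 3.41 to 15.3 ± 1.92 CPM. On the mm10 build, Mmp8 lies on chromosome 9 from 7558429 to 7568486, Gfi1b on chromosome 2 from 28609450 to 28621982, and Ptgfrn on chromosome 3 from 101040236 to 101110166. Ctss lies on chromosome 3 from 95526786 to 95556403 and Ms4a4c on chromosome 19 from 11407661 to 11427246. Fcnb lies on chromosome 2 from 28076479 to 28084878, Car2 on chromosome 3 from 14886426 to 14900770, and Tuba8 on chromosome 6 from 121210770 to 121226097. Myh7b, on chromosome 2 from 155611212 to 155634307, overlaps Trpc4ap and Mir499, and whether counting separated the strands is not given in the sources used here. Rtn4rl2 lies on chromosome 2 from 84871946 to 84886692.

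**Figure D1:**
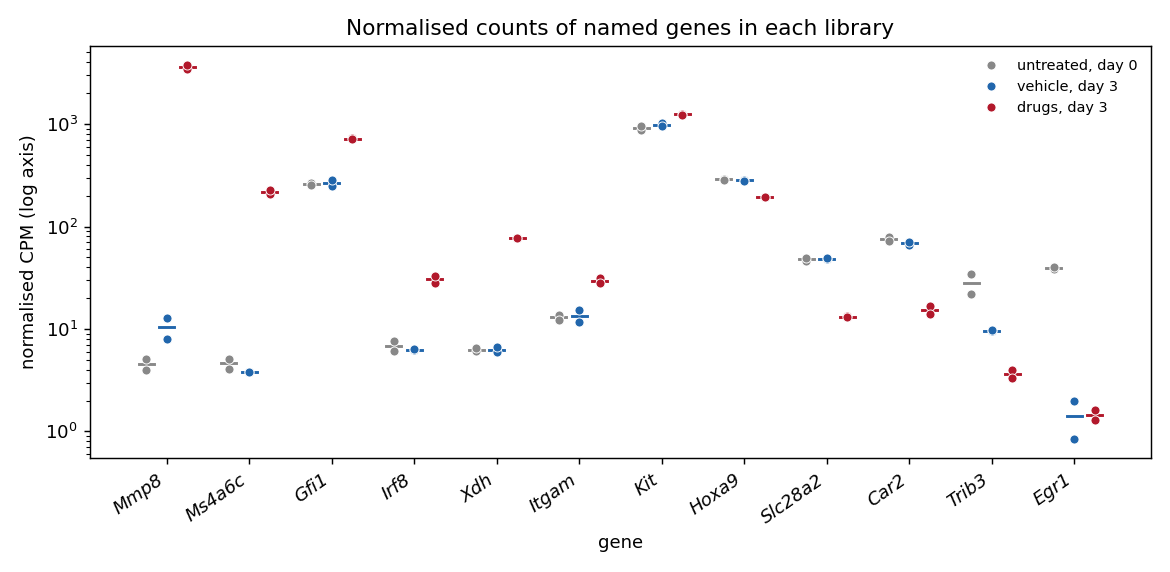
Normalised read counts in CPM (log axis) of genes named by the rule in each library, with a dot per library and a line at each group mean. Mmp8 averaged 4.54 CPM at day 0, 10.35 CPM with vehicle and 3642 CPM with the drugs.

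Of 11283 genes tested, 2041 were higher and 1560 lower with the drugs than with vehicle. Changes over 2-fold were made up of 629 rises and 122 falls, and 203 of those rises started from under 1 CPM with vehicle. DESeq2 called 1316 higher and 1005 lower, and a test against a minimum of 1.5-fold left 599 and 115. With scaling by library totals 1644 were higher and 1695 lower, so that 49.2% rather than 56.7% of the called genes were higher. The counts were 1251 higher and 582 lower without drug replicate 1, and 1348 and 708 without drug replicate 2.

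Secondary granule and mature neutrophil genes were called higher as lists, though abundant transcripts of mature neutrophils stayed near 0. Of the neutrophil secondary granule genes, 5 of 14 had enough counts to test, and 4 rose and 0 fell, both over all genes and adjusted over the list alone (median log2 change 2.30, adjusted p = 6.87e-24; adjusted p = 0.0738 with an estimated correlation). Besides Mmp8, Anxa1, an inflammation-limiting annexin, rose by 2.30 ± 0.0931, and Chil3, a chitinase-like protein of myeloid cells, by 3.09 ± 0.151. The granule genes Ltf and Ngp had at most 2 counts in any of the 6 libraries, Camp had 0, and S100a8 had at most 23. Lyz2 was listed at 0 in all 6, but how reads with several matches were handled is not given, so its level is uncertain. Of 18 tested mature neutrophil genes, 14 rose and 1 fell, also when adjusted over the list alone (median 0.63, adjusted p = 1.8e-12; adjusted p = 0.0738 with an estimated correlation). Hdc, which makes histamine, rose by 2.84 ± 0.0994, while Clec4e, a C-type lectin that senses mycobacterial glycolipid, was the member that fell. Mmp9 reached only 5.19 CPM with the drugs after a log2 rise of 5.3, so it could hardly have been called lower. Of 10 primary granule genes, made earlier in granulopoiesis, 4 rose and 3 fell (4 and 3 adjusted over the list alone), and the list was not called (adjusted p = 0.771). Mpo, the myeloperoxidase gene, rose by 0.54 ± 0.104 and Nkg7, a granule membrane protein, by 1.87 ± 0.191.

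The monocyte and macrophage list and the myeloid receptor list were called higher. Of 19 tested monocyte and macrophage genes, 14 rose and 3 fell, also when adjusted over the list alone (median 1.40, adjusted p = 3.96e-23; adjusted p = 0.0738 with an estimated correlation). Ms4a6c, an MS4A protein of monocytes, rose from 3.82 ± 0.0366 to 216.4 ± 12.7 CPM (log2 change 5.82 ± 0.112). The falls were F13a1, coagulation factor XIII, Cx3cr1, the fractalkine receptor, and Cd63, a granule tetraspanin. The macrophage complement genes C1qa and C1qc had 0 counts in all 6 libraries. Members near 0 with vehicle, such as Ctss and Fn1, could hardly be called lower, so the count of 14 is partly built in. Fn1 reached only 1.38 CPM with the drugs after a log2 rise of 4.81. Of 18 tested myeloid surface and Fc receptor genes, 11 rose and 0 fell, or 12 and 0 adjusted over the list alone (median 0.69, adjusted p = 1.22e-09; adjusted p = 0.248 with an estimated correlation). Siglece, an inhibitory sialic acid receptor, rose by 7.01 ± 0.19, Pirb, an inhibitory receptor for MHC class I, by 2.53 ± 0.302, and Clec12a, another inhibitory lectin receptor, by 1.69 ± 0.0863. Itgam, which encodes the myeloid integrin CD11b, rose from 13.5 ± 2.43 to 29.6 ± 2.27 CPM (log2 change 1.13 ± 0.13, adjusted p = 2.58e-05).

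The myeloid transcription factor, GFI1 target and LSD1 complex lists were called higher, the last only with shared genes included. Of 25 myeloid transcription factor genes, 14 rose and 2 fell, also when adjusted over the list alone (adjusted p = 5.04e-08; adjusted p = 0.0738 with an estimated correlation). Irf8, which drives monocyte fate, rose from 6.3 ± 0.0774 to 30.5 ± 3.1 CPM (log2 change 2.28 ± 0.141, adjusted p = 7.75e-08), and Gfi1, the paralog of Gfi1b and a driver of neutrophil fate, rose by 1.44 ± 0.0819. The 2 falls were Cebpa, a granulocyte fate factor, and Junb, an AP-1 subunit. Spi1, which encodes PU.1, rose by 0.34 ± 0.0737 (adjusted p = 0.00397), a call that was lost without drug replicate 1 (adjusted p = 0.062). Of 17 genes listed as GFI1 repression targets, 9 rose and 1, Hoxa9, fell, also when adjusted over the list alone (adjusted p = 1.21e-07; adjusted p = 0.0738 with an estimated correlation). Among them Csf1r, the receptor for the macrophage growth factor, rose by 3.17 ± 0.182. The LSD1 complex list was called higher (adjusted p = 0.017; adjusted p = 0.248 with an estimated correlation), with 3 rises and 3 falls among 16 genes, also when adjusted over the list alone. Its rises were Gfi1b, Gfi1 and Phf21a, a reader of unmethylated histone H3, and its falls were the corepressors Rcor1 and Rcor2 and the deacetylase Hdac2. Without the genes it shares with other lists its call was lost and its direction turned (median -0.014, adjusted p = 0.651). Kdm1a, which encodes LSD1 itself (chromosome 4, 136550533 to 136602723), was not called (log2 change -0.11 ± 0.0767, adjusted p = 0.288).

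The NF-kB, lysosome, interferon and MHC class II lists were called higher. Of 22 NF-kB and inflammatory cytokine genes, 13 rose and 2 fell, also when adjusted over the list alone (adjusted p = 4.19e-05; adjusted p = 0.248 with an estimated correlation). Nlrp3, the inflammasome sensor, rose from 1.84 ± 0.475 to 54.8 ± 3.19 CPM (log2 change 4.90 ± 0.157), Icam1, an adhesion molecule, rose by 1.76 ± 0.152, and Tnfsf13b, the B cell survival factor BAFF, by 3.44 ± 0.395. Ptgs2, the inducible cyclooxygenase, and the chemokine Ccl9 fell. Of 32 lysosome genes, 18 rose and 1 (Cd63) fell, or 19 and 2 adjusted over the list alone (median 0.36, adjusted p = 7.89e-05; adjusted p = 0.361 with an estimated correlation). Psap, the precursor of the saposins, rose by 1.22 ± 0.0752 and Lipa, the lysosomal acid lipase, by 1.19 ± 0.0853. Of 29 interferon-stimulated genes, 15 rose and 2 fell, also when adjusted over the list alone (median 0.57, adjusted p = 0.00868; adjusted p = 0.361 with an estimated correlation). Of 5 MHC class II genes, 4 rose and 0 fell, also when adjusted over the list alone (adjusted p = 0.0365; adjusted p = 0.307 with an estimated correlation), a call lost without untreated replicate 1 (adjusted p = 0.0509), untreated replicate 2 (0.0502) or vehicle replicate 2 (0.0595).

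Lists of ribosome biogenesis, the ATF4 response, purine synthesis and DNA replication were called lower. Of 39 ribosome biogenesis genes, 24 fell and 2 rose, or 27 and 2 adjusted over the list alone (median -0.29, adjusted p = 1.66e-05; adjusted p = 0.361 with an estimated correlation). Rrp12, a ribosome export factor, fell by 0.67 ± 0.0898 and Polr1b, a subunit of RNA polymerase I, by 0.57 ± 0.0833, whereas Polr1e, another subunit, rose by 0.60 ± 0.123. Of 28 genes of the ATF4 integrated stress response, which supplies amino acids and charged tRNAs under stress, 15 fell and 0 rose, also when adjusted over the list alone (median -0.33, adjusted p = 3.25e-05; adjusted p = 0.361 with an estimated correlation). Wars, the tryptophanyl-tRNA synthetase, fell by 0.71 ± 0.0811, Asns, asparagine synthetase, changed by -0.95 ± 0.122, and Trib3, a pseudokinase induced by ATF4, changed by -1.40 ± 0.26. Of 23 genes of purine de novo synthesis and one-carbon metabolism, 14 fell and 2 rose, also when adjusted over the list alone (median -0.31, adjusted p = 0.00648; adjusted p = 0.361 with an estimated correlation). Shmt2, the mitochondrial serine hydroxymethyltransferase, changed by -0.47 ± 0.0686 and Impdh1, an enzyme of guanine nucleotide synthesis, by -0.45 ± 0.0737. Of 39 DNA replication genes, 13 fell and 1 rose, or 15 and 1 adjusted over the list alone (median -0.19, adjusted p = 0.00648; adjusted p = 0.361 with an estimated correlation). Mcm2, a helicase subunit, changed by -0.43 ± 0.0678, and the rise was E2f2, a cell cycle transcription factor (0.76 ± 0.111).

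Smaller downward calls covered 3 more lists. Of 44 mitosis genes, 11 fell and 1 rose, also when adjusted over the list alone (median -0.10, adjusted p = 0.0231; adjusted p = 0.248 with an estimated correlation). Of 32 oxidative phosphorylation genes, 9 fell and 0 rose, or 8 and 0 adjusted over the list alone (adjusted p = 0.017; adjusted p = 0.69 with an estimated correlation), a call lost without vehicle replicate 2 (adjusted p = 0.0912) and with fry (0.158). Of 18 genes of pyrimidine and deoxynucleotide synthesis, 7 fell and 1 rose, also when adjusted over the list alone (adjusted p = 0.0276; adjusted p = 0.307 with an estimated correlation). That call was lost without drug replicate 1 (adjusted p = 0.0576) or vehicle replicate 2 (0.0697). Mki67, a proliferation marker, was not called (-0.07 ± 0.086, adjusted p = 0.589), nor was Myc (-0.10 ± 0.079, adjusted p = 0.361).

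**Figure D2:**
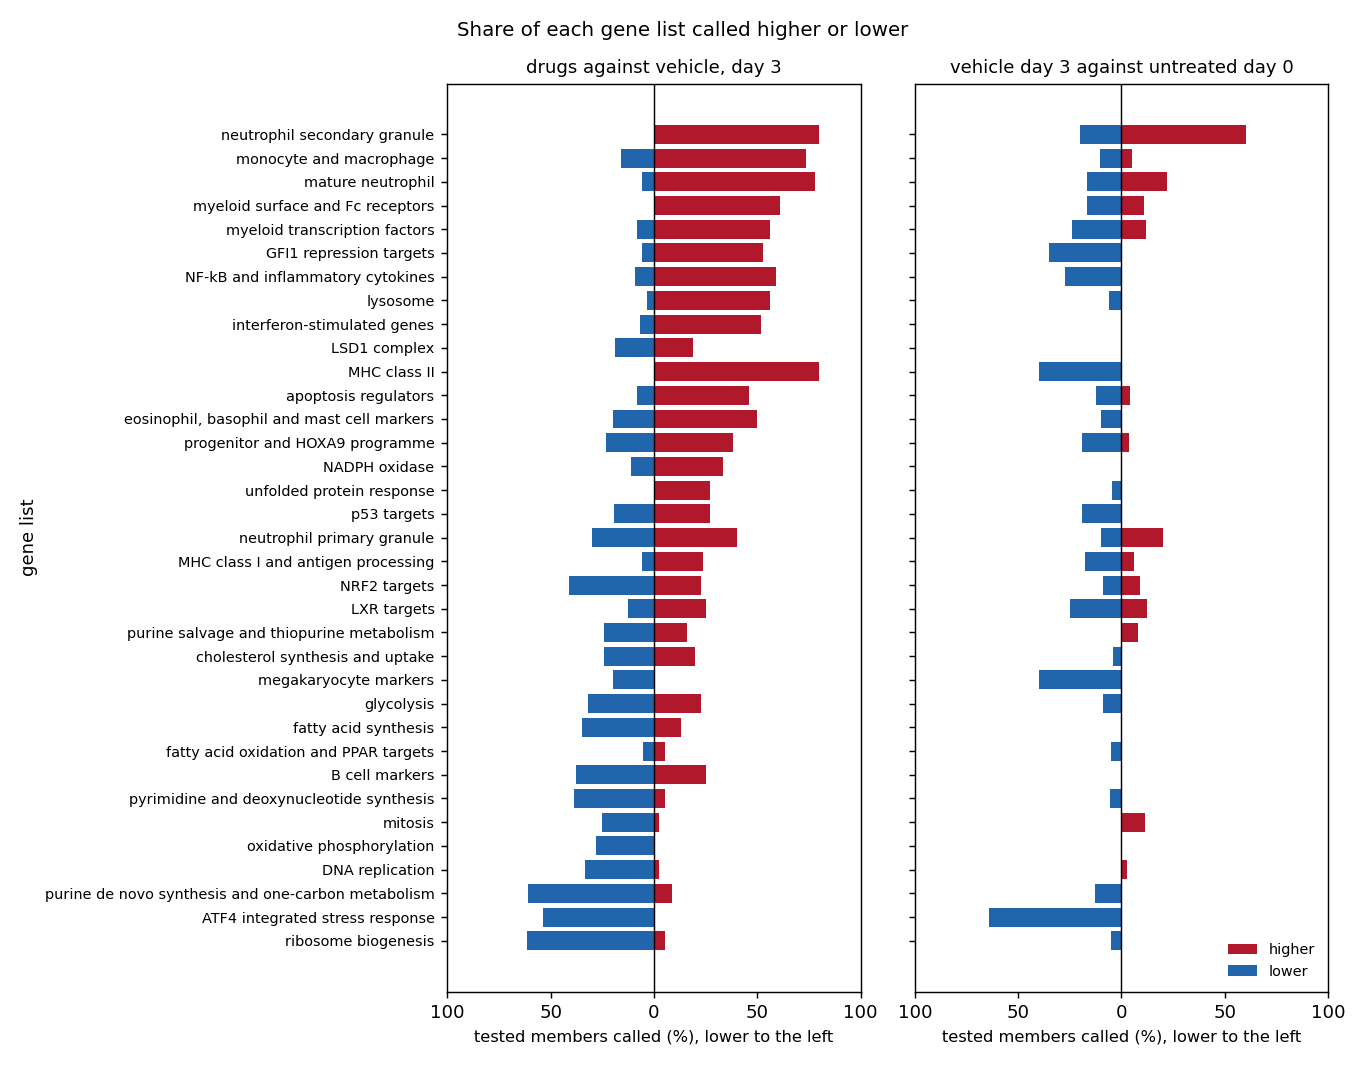
Share of the tested members of each gene list called higher (bars to the right, in percent) and lower (bars to the left). Lists large enough for a list test are shown, for drug versus vehicle and for vehicle versus day 0. In drug versus vehicle, 14 of 19 monocyte and macrophage genes were higher and 15 of 28 ATF4 genes lower.

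Genes of the drugs' own pathways differed from one another. Fasn, the fatty acid synthase that cerulenin inhibits, was not called (log2 change -0.24 ± 0.109, adjusted p = 0.12). It was called lower with library totals (0.0465), no filter (0.0116), only the 2 groups (0.0289), and without untreated replicate 1 (0.0318), untreated replicate 2 (0.033) or vehicle replicate 2 (0.0319). Hprt, the salvage enzyme that activates mercaptopurine, was not called (-0.10 ± 0.0719, adjusted p = 0.311), nor was Tpmt, which inactivates it (0.74 ± 0.344, adjusted p = 0.122). Of 25 genes of purine salvage and thiopurine metabolism, 4 rose and 6 fell, also when adjusted over the list alone, and the list was not called (adjusted p = 0.767). Among them Xdh, xanthine dehydrogenase, which oxidises mercaptopurine, rose from 6.31 ± 0.422 to 77.3 ± 1.08 CPM (log2 change 3.62 ± 0.105), and Slc28a2, a purine nucleoside transporter, changed by -1.88 ± 0.0916. Of 23 fatty acid synthesis genes, 3 rose and 8 fell, also when adjusted over the list alone (adjusted p = 0.323), with Elovl7, a fatty acid elongase, higher by 1.38 ± 0.188. Cholesterol synthesis and uptake had 5 rises and 6 falls among 25 genes, also when adjusted over the list alone (adjusted p = 0.453), and its median of 0.026 differed in sign from its mean of -0.024 and its downward test.

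Progenitor genes split. Of 26 genes of the progenitor and HOXA9 programme, 10 rose and 6 fell, or 11 and 7 adjusted over the list alone, and the list was not called (adjusted p = 0.479). Hoxa9 transcript, which the table does not separate into fusion and endogenous copies, went from 281.5 ± 8.83 to 192.9 ± 0.723 CPM (log2 change -0.55 ± 0.0696, adjusted p = 6.44e-05). It is annotated on chromosome 6 from 52224054 to 52227370. Meis1, a HOXA9 cofactor, was not called (-0.09 ± 0.083, adjusted p = 0.462). Satb1, a chromatin organiser, rose by 1.76 ± 0.0892, Flt3, a progenitor receptor kinase, by 0.90 ± 0.0703, and Mycn changed by -2.49 ± 0.196. Kit, the stem cell factor receptor, rose by 0.33 ± 0.083 (adjusted p = 0.00865), a call lost without drug replicate 1 (adjusted p = 0.116), vehicle replicate 2 (0.0907) or drug replicate 2 (0.0791). Cdkn1a, the p21 inhibitor of cell division, rose by 0.50 ± 0.149 (adjusted p = 0.0212), a call lost with DESeq2 (0.178), without drug replicate 1 (0.0687), without vehicle replicate 2 (0.132) and without drug replicate 2 (0.164). Cd86, an activation marker of myeloid cells, had at most 3 counts in any library and was not tested.

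The other lists were not called by camera in this comparison. Of the lists it did not call, fry, which does not compare a list with other genes, called apoptosis regulators higher (adjusted p = 0.00264), eosinophil, basophil and mast cell markers higher (0.023) and B cell markers lower (0.0075). The p53 target list had 7 rises and 5 falls among 26 genes (8 and 6 adjusted over the list alone), NRF2 targets 5 and 9 among 22 (5 and 12 adjusted over the list alone), and the unfolded protein response 6 and 0 among 22 (6 and 0). For NRF2 targets the median of -0.18 differed in sign from the mean of 0.25 and the upward test (adjusted p = 0.87), and Mgst1, a microsomal glutathione transferase, rose by 6.04 ± 0.177. Apoptosis regulators had 11 rises and 2 falls among 24 genes (12 and 2 adjusted over the list alone; adjusted p = 0.226). Glycolysis had 5 and 7 among 22 (7 and 8), MHC class I and antigen processing 4 and 1 among 17 (4 and 1), and NADPH oxidase 3 and 1 among 9 (3 and 1). LXR targets had 2 rises and 1 fall among 8 genes (2 and 2), and fatty acid oxidation and PPAR targets 1 and 1 among 19 (1 and 1).

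Markers of other blood and tissue cells were few and mixed. Of the eosinophil, basophil and mast cell markers, 5 of 10 rose and 2 fell (5 and 2 adjusted over the list alone), with Cpa3, the mast cell carboxypeptidase, higher by 1.32 ± 0.098 and Prg2, the eosinophil major basic protein, at -1.98 ± 0.152. Of 8 B cell markers, 2 rose and 3 fell (2 and 3), including Igll1, a surrogate light chain (-1.78 ± 0.15), and Ebf1, a B cell fate factor (-0.97 ± 0.106). Megakaryocyte markers had 0 rises and 1 fall, Gp9, among 5 genes (0 and 1), with a median of 0.097 against a mean of -0.61 and a downward test (adjusted p = 0.453). Erythroid markers, Car2 among them, had 2 falls among 3 tested genes, dendritic cell markers 2 rises among 3, T and NK cell markers 1 fall among 2, and stromal and epithelial markers 2 rises among 4 (3 adjusted over the list alone). These last 4 lists were too small for a list test. The effects of the single drugs were not separable, because the 3 were given only together.

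The comparison of vehicle at day 3 with untreated cells gave the background of 3 days in culture with DMSO. The 2 groups differ in both day and solvent, so these cannot be told apart. Changes described below as in culture cover both. The ATF4 and NF-kB lists were called lower after culture, while no granule list was called. Egr1, an immediate-early transcription factor on chromosome 18 from 34861207 to 34864956, went from 39.6 ± 0.945 to 1.41 ± 0.806 CPM (log2 change -4.79 ± 0.202, adjusted p = 7.74e-08). Fcnb rose by 2.44 ± 0.165 (adjusted p = 6.81e-06), and Dgat2, an enzyme of triglyceride synthesis on chromosome 7 from 99153663 to 99182713, by 2.29 ± 0.145. Elane, the neutrophil elastase gene on chromosome 10 from 79886312 to 79888216, rose by 1.69 ± 0.162, from 10.3 ± 0.255 to 33.3 ± 9.02 CPM. Abca13, a lipid transporter, rose by 1.83 ± 0.183 and Mtus1, a microtubule-binding protein, by 1.59 ± 0.0877. Avil, an actin-binding protein (chromosome 10, 127000709 to 127020994), changed by -2.40 ± 0.268, Arrdc3, an arrestin-like adaptor, by -1.69 ± 0.136, and Trib3 by -1.58 ± 0.19. Mamdc2, a matrix proteoglycan gene, changed by -1.88 ± 0.345, but by -1.13 without untreated replicate 1.

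In all, 423 genes were higher and 450 lower after culture with vehicle, and 40 and 92 of them changed over 2-fold. With scaling by library totals the counts were 1741 higher and 216 lower, so that 89% rather than 48.5% of the called genes were higher, and the median of all genes moved from -0.0173 to 0.104. Rn45s took 15.4% of counts with vehicle against 22.5% at day 0. DESeq2 called 243 and 218. A replicate block gave 222 and 261, a block with the vehicle numbers exchanged 1627 and 1498, no filter 821 and 843, and only the 2 groups 269 and 258. The counts were 162 and 197 without untreated replicate 1, 851 and 1161 without untreated replicate 2, 155 and 196 without vehicle replicate 1, 252 and 278 without drug replicate 1, and 249 and 286 without drug replicate 2.

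The ATF4, NF-kB and GFI1 target lists were called lower in culture by camera. Among the called lists fry kept only the GFI1 targets, with adjusted p = 0.0868 for both others named here. Of 28 ATF4 genes, 18 fell and 0 rose, or 23 and 0 adjusted over the list alone (median -0.43, adjusted p = 2.62e-17; adjusted p = 0.427 with an estimated correlation). Besides Trib3, Ppp1r15a, a phosphatase subunit that ends the stress response, changed by -1.43 ± 0.148, and Aldh1l2, a mitochondrial folate enzyme, by -2.19 ± 0.339. Of 22 NF-kB and inflammatory cytokine genes, 6 fell and 0 rose, or 10 and 0 adjusted over the list alone (adjusted p = 5.39e-06; adjusted p = 0.427 with an estimated correlation). Nfkbiz, a nuclear regulator of NF-kB, changed by -0.79 ± 0.113, Ptgs2 by -1.35 ± 0.198 and the chemokine Ccl3 by -1.48 ± 0.243. Of 17 GFI1 repression targets, 6 fell and 0 rose, also when adjusted over the list alone (adjusted p = 2.79e-08; adjusted p = 0.258 with an estimated correlation), among them Egr1 and Itga2b, the platelet integrin (-1.27 ± 0.167).

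Itga2b was also 1 of 2 megakaryocyte markers that fell, with 0 rises among 5, or 4 and 0 adjusted over the list alone (median -0.57, adjusted p = 0.00287; adjusted p = 0.427 with an estimated correlation). Of 10 eosinophil, basophil and mast cell markers, 1 (Cpa3, -1.07 ± 0.0975) fell and 0 rose, or 4 and 1 adjusted over the list alone (adjusted p = 0.0136; adjusted p = 0.427 with an estimated correlation). Myeloid transcription factors had 3 rises and 6 falls among 25, or 3 and 9 adjusted over the list alone. Their test was downward (adjusted p = 0.0136; adjusted p = 0.427 with an estimated correlation) with a median of 0.0091 and a mean of -0.44, and the call was lost without untreated replicate 2 (adjusted p = 0.126). The median of the full list was -0.16 without untreated replicate 1, -0.07 without vehicle replicate 1, -0.072 without vehicle replicate 2 and -0.046 without drug replicate 2. Without the genes shared with other lists the call was lost and the test turned upward (median 0.0939, adjusted p = 0.787). Cebpe, a factor for granule gene expression, rose by 0.62 ± 0.0921. Among key genes Meis1 was lower (-0.38 ± 0.0806, adjusted p = 0.0134), a call lost with DESeq2 (0.0799), with library totals (0.0656), without untreated replicate 1 (0.0621) and without vehicle replicate 2 (0.0702). Kdm1a, Hprt, Tpmt, Fasn, Hoxa9, Itgam, Spi1, Irf8, Kit, Myc, Mki67 and Cdkn1a were not called. With library totals Fasn (adjusted p = 0.0413), Kit (0.0262), Myc (0.00502) and Mki67 (0.00912) were called higher. So were Myc with no filter (0.0286), Myc (0.0192) and Fasn (0.0374) without untreated replicate 2, and Fasn (0.00182), Myc (3.06e-05) and Mki67 (0.000953) with a replicate block in which the vehicle numbers were exchanged.

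The other 4 downward list calls each depended on scaling or on single libraries, with an adjusted p = 0.692 with an estimated correlation for every one. Ribosome biogenesis had 2 falls among 39 genes (0 adjusted over the list alone; adjusted p = 0.0136), with 0.138 under library totals and 0.173 without untreated replicate 2. MHC class I and antigen processing had 3 falls and 1 rise among 17 (7 and 1 adjusted over the list alone; adjusted p = 0.0296), with 0.115 under library totals and 0.228 without untreated replicate 1. Oxidative phosphorylation had 0 falls and 0 rises among 32 (0 and 0 adjusted over the list alone; adjusted p = 0.0307), with 0.154 under library totals, 0.391 without untreated replicate 1 and 0.291 without vehicle replicate 1. Glycolysis had 2 falls among 22 (4 adjusted over the list alone; adjusted p = 0.0405), and its call was lost under library totals (0.138), with a replicate block (0.0575) and without drug replicate 1 (0.0783), untreated replicate 2 (0.342), vehicle replicate 2 (0.252) or drug replicate 2 (0.0538). Without vehicle replicate 1, 16 rather than 10 lists were called.

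The granule, mature neutrophil and monocyte lists were not called between vehicle and day 0. Secondary granule genes had 3 rises and 1 fall among 5 (3 and 2 adjusted over the list alone), mature neutrophil genes 4 and 3 among 18 (5 and 3), and monocyte and macrophage genes 1 and 2 among 19 (3 and 2). Primary granule genes had 2 and 1 among 10 (3 and 3), and DNA replication genes 1 and 0 among 39 (0 and 0). Mitosis genes had 5 rises and 0 falls among 44 (5 and 1). The unfolded protein response had 0 rises and 1 fall among 22 (0 and 3; adjusted p = 0.387), and NRF2 targets had 2 and 2 among 22 (3 and 2; adjusted p = 0.387). The median and the test differed in sign for purine salvage and thiopurine metabolism (median -0.043, upward test, adjusted p = 0.905) and for NADPH oxidase (median -0.04, mean 0.0051, upward, adjusted p = 0.678). For the LSD1 complex the mean of -0.12 lay below 0, while the median of 0.036 and the test (adjusted p = 0.56) were upward.

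Histone genes formed a family that was defined after the values were seen. Of 57 tested, 42 rose and 0 fell between day 0 and vehicle (median 0.71; Fisher's exact test, two-sided, adjusted p = 1.87e-46), and 48 and 0 did so with library totals. Most transcripts of replication-dependent histone genes lack a poly(A) tail, and near-identical copies make single members uncertain. The exact test counts such copies as independent genes, so its p values for this family overstate the evidence. Between vehicle and drugs 32 fell and 1, Hist2h2be, rose (median -0.41; Fisher's exact test, adjusted p = 2.96e-12), and 30 fell and 0 rose with library totals. Between day 0 and drugs 28 rose and 0 fell (median 0.39; Fisher's exact test, adjusted p = 0.000251), and 31 and 0 did so with library totals. Their summed level was 644.1 ± 62.6 CPM at day 0, 1186 ± 90.5 with vehicle and 858.2 ± 24.2 with the drugs.

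**Figure D3:**
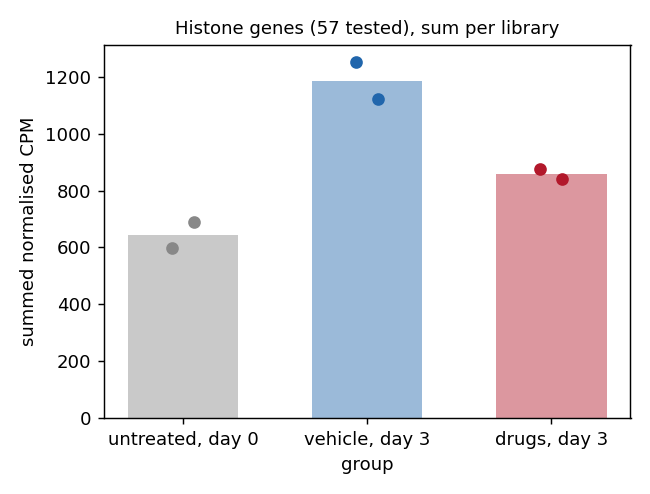
Summed normalised read counts (CPM) of the tested histone genes, with a dot per library and a bar from 0 to the mean of each group. The mean was 644.1 CPM at day 0, 1186 CPM with vehicle and 858.2 CPM with the drugs.

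The third comparison set the drug-treated cells against the untreated cells they started from. Secondary granule and monocyte lists were called higher than at day 0, and the ATF4 list was called lower. Mmp8 rose from 4.54 ± 0.75 to 3642 ± 223 CPM (log2 change 9.67 ± 0.189, adjusted p = 1.71e-12), Siglece by 8.34 ± 0.213 and Mgst1 by 8.13 ± 0.217. Gfi1b rose by 8.26 ± 0.178 from 0.274 ± 0.0352 CPM. Ptgfrn again had 0 counts in both reference libraries. Avil changed by -4.84 ± 0.365, Egr1 by -4.78 ± 0.195, Trib3 by -2.99 ± 0.22 and Tuba8 by -2.87 ± 0.106.

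Of the tested genes, 2564 were higher and 2394 lower than at day 0, with 680 and 236 over 2-fold. With library totals 3141 were higher and 1321 lower, so that 70.4% rather than 51.7% of called genes were higher, and the median of all genes moved from -0.00752 to 0.0829. Rn45s was lower by this comparison (log2 change -0.61 ± 0.197, adjusted p = 0.0234). DESeq2 called 1768 genes higher and 1585 lower. Fewer genes were called in both directions when drug replicate 1 or drug replicate 2 was left out.

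All 5 tested secondary granule genes rose, also when adjusted over the list alone (adjusted p = 8.08e-20; adjusted p = 0.144 with an estimated correlation), with Chil3 higher by 4.23 ± 0.169. Only 5 of the 14 listed genes could be tested. The granule genes Ltf, Ngp and Camp stayed at or near 0 counts in all 6 libraries. Of 10 primary granule genes, 4 rose and 3 fell (4 and 3 adjusted over the list alone), and the list was not called (adjusted p = 0.298). Of 19 monocyte and macrophage genes, 13 rose and 3 fell, or 14 and 3 adjusted over the list alone (adjusted p = 1.69e-17; adjusted p = 0.118 with an estimated correlation), and Ms4a6c rose by 5.53 ± 0.106. Of 18 mature neutrophil genes, 14 rose and 1 fell, also when adjusted over the list alone (median 0.90, adjusted p = 1.2e-10; adjusted p = 0.118 with an estimated correlation), with Hdc higher by 2.73 ± 0.0961. Of 28 ATF4 genes, 27 fell and 0 rose, also when adjusted over the list alone (median -0.71, adjusted p = 1.1e-14; adjusted p = 0.322 with an estimated correlation), with Wars at -1.12 ± 0.0799. Of 39 ribosome biogenesis genes, 32 fell and 2 rose, or 34 and 2 adjusted over the list alone (median -0.39, adjusted p = 1.76e-07; adjusted p = 0.335 with an estimated correlation). Rrs1 and Nolc1, factors of ribosomal subunit assembly and the nucleolus, changed by -0.71 ± 0.0733 and -0.62 ± 0.0751.

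Key genes moved in part. Hoxa9 changed by -0.58 ± 0.0695 (adjusted p = 2.8e-05) and Meis1 by -0.47 ± 0.0801 (adjusted p = 0.000527). Irf8 rose by 2.18 ± 0.136, Itgam by 1.18 ± 0.127, Spi1 by 0.48 ± 0.0735 and Kit by 0.44 ± 0.083. Hprt was lower (-0.21 ± 0.0711, adjusted p = 0.0273), a call lost with library totals (0.157), with DESeq2 (0.104), with a replicate block (0.0574), and without drug replicate 1 (0.247), drug replicate 2 (0.0705) or untreated replicate 2 (0.0515). Cdkn1a was higher (0.47 ± 0.145, adjusted p = 0.0189), a call lost with DESeq2 (0.16) and without untreated replicate 1 (0.104), drug replicate 1 (0.0597) or drug replicate 2 (0.153). Kdm1a, Fasn, Tpmt, Myc and Mki67 were not called, though with library totals Myc (0.0123) and Mki67 (0.0155) were called higher. Of the remaining lists called higher, myeloid surface and Fc receptor genes had 10 rises and 1 fall among 18 (11 and 1 adjusted over the list alone; adjusted p = 3.02e-07; adjusted p = 0.322 with an estimated correlation). Myeloid transcription factors had 12 and 8 among 25 (12 and 8; adjusted p = 0.000639; adjusted p = 0.217 with an estimated correlation). Lysosome genes had 20 and 2 among 32 (20 and 3; adjusted p = 0.00491; adjusted p = 0.536 with an estimated correlation). The LSD1 complex had 5 and 3 among 16 (5 and 3; adjusted p = 0.0138; adjusted p = 0.322 with an estimated correlation), and without the genes it shares with other lists its call was lost and its direction turned (median -0.02, adjusted p = 0.908). GFI1 repression targets had 7 rises and 5 falls among 17 (7 and 5; adjusted p = 0.0488; adjusted p = 0.335 with an estimated correlation). That call was lost with library totals (0.0853) and without untreated replicate 1 (0.112), untreated replicate 2 (0.0904), vehicle replicate 1 (0.0615) or vehicle replicate 2 (0.0631).

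Of the remaining lists called lower against day 0, oxidative phosphorylation had 19 falls and 0 rises among 32 genes (21 and 0 adjusted over the list alone; adjusted p = 0.0012; adjusted p = 0.543 with an estimated correlation), a call lost with fry (0.0502). Purine de novo synthesis and one-carbon metabolism had 14 and 3 among 23 (14 and 3; adjusted p = 0.00487; adjusted p = 0.361 with an estimated correlation). Pyrimidine and deoxynucleotide synthesis had 9 and 0 among 18 (9 and 0; adjusted p = 0.0193; adjusted p = 0.335 with an estimated correlation). Megakaryocyte markers had 3 falls and 0 rises among 5 (4 and 0; adjusted p = 0.0295; adjusted p = 0.535 with an estimated correlation), a call lost without untreated replicate 1 (adjusted p = 0.0523). Of the lists called between vehicle and drugs, 5 were not called against day 0 by camera, although fry called each. NF-kB genes had 8 rises and 5 falls among 22 (9 and 5 adjusted over the list alone; adjusted p = 0.138, fry 0.012), and interferon-stimulated genes 11 and 2 among 29 (11 and 2; 0.0953, fry 0.0133). DNA replication had 2 and 13 among 39 (2 and 13; 0.109, fry 0.0382), mitosis 6 and 12 among 44 (6 and 12; 0.309, fry 0.0376), and MHC class II 2 and 0 among 5 (2 and 0; 0.315, fry 0.00785). The median differed in sign from the mean and the test for MHC class II (median -0.093, mean 0.63, upward, adjusted p = 0.315), NRF2 targets (median -0.18, mean 0.30, upward, adjusted p = 0.647) and LXR targets (median 0.044, mean -0.11, downward, adjusted p = 0.453). For p53 targets the mean of 0.073 differed from the median of -0.088 and the downward test (adjusted p = 0.648).

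The last comparison asked how the drug response overlapped with the change in culture. Genes that fell in culture and rose with the drugs numbered 156, against 81.4 for independent lists, and included Anxa1, Cpa3 and Trp53inp1, a stress-induced autophagy protein. Genes that rose in both numbered 120 (76.5 for independent lists) and included Flt3, and 68 fell in both (62.2), among them Avil and Trib3. Another 83 rose in culture and fell with the drugs (58.5), among them Fcnb. In all, 188 genes moved in the same direction and 239 in opposite directions, 315 and 476 with library totals, and 15 and 25 among changes over 2-fold. The same 2 vehicle libraries enter both comparisons with opposite sign. The log2 changes had a covariance across genes of -0.0331 and a correlation of -0.131, where 50 simulations of unchanged groups that shared the vehicle libraries gave -0.0176 and -0.526, and genes are not independent replicates. With vehicle replicate 1 only in the drug comparison and vehicle replicate 2 only in the culture comparison, 96 moved in the same and 94 in opposite directions (43.9 and 44.8 for independent lists; covariance -0.0356). With the 2 exchanged, the counts were 178 and 121 (104 and 99.5; covariance -0.0222). Same-direction and opposite counts were 104 and 124 without untreated replicate 1, 359 and 486 without untreated replicate 2, 83 and 104 without vehicle replicate 1, 83 and 115 without drug replicate 1, and 86 and 111 without drug replicate 2, and 113 moved in the same direction without vehicle replicate 2.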

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

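The fits without Rn45s, the exchanged replicate block, and the overlap with each library left out or the vehicle libraries split, were chosen after the results were seen. Of 5143 alternatives over 316 results of named genes, 4649 kept direction and side of the threshold, 448 lost a call, 29 gained one and 17 changed direction, all 17 for genes that were not called. Where a library was left out, its group's remaining library was assumed to vary like the other groups. No call of a list was kept with an estimated correlation (0 lists in each comparison), while fry called 20, 1 and 23 in drug versus vehicle, vehicle versus day 0 and drug versus day 0. Lists not called showed another direction in 31 of 755 alternatives, with 0 of those called. limma-voom, DESeq2 size factors, the stricter filter and leaving out Rn45s moved no count over 1.5 times. Except where an alternative's construction shows it, the cause was not tested.

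DESeq2 called 1316 higher and 1005 lower in drug versus vehicle (2307 of the 3601 genes shared). It called 243 and 218 in vehicle versus day 0 (454 of 873 shared), and 1768 and 1585 in drug versus day 0 (3332 of 4958 shared). Library totals gave 1741 and 216 in vehicle versus day 0, and 3141 and 1321 in drug versus day 0. For vehicle versus day 0, no filter gave 821 and 843, a replicate block 222 and 261, the exchanged block 1627 and 1498, and only the 2 groups 269 and 258. A minimum of 1.5-fold, a stricter test by construction, left 599 and 115 in drug versus vehicle, 23 and 33 in vehicle versus day 0, and 647 and 239 in drug versus day 0. The overlap fell to 15 same and 25 opposite among changes over 2-fold and was 315 and 476 with library totals. With the vehicle libraries split so that the comparisons shared none, 96 and 94 were counted with replicate 1 in drug versus vehicle, and 178 and 121 with replicate 2, where fewer libraries entered each comparison by construction.

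Leaving out each library gave 1251 to 2291 higher and 582 to 1900 lower genes in drug versus vehicle, 155 to 851 and 196 to 1161 in vehicle versus day 0 (7 to 16 lists), and 1667 to 2632 and 1205 to 2625 in drug versus day 0. The overlap ranged from 83 to 359 in the same and from 104 to 486 in opposite directions.

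Changes of direction with library totals were Hprt 0.00889, Hoxa9 0.0842, Irf8 0.0265 and Cdkn1a 0.0863 in vehicle versus day 0, and Kdm1a 0.00261 and Fasn 0.0402 in drug versus day 0. Without shared genes 3 list calls were lost with a change of direction. The LSD1 complex median was -0.014 in drug versus vehicle (adjusted p = 0.651) and -0.0201 in drug versus day 0 (0.908), because Gfi1b and Gfi1 left it, and that of myeloid transcription factors was 0.0939 in vehicle versus day 0 (0.787). Leaving out each library, values of 8 uncalled genes crossed 0. In vehicle versus day 0 they ranged from -0.000254 to 0.0583 for Kdm1a, -0.125 to 0.204 for Tpmt, -0.133 to 0.224 for Itgam, -0.264 to 0.0537 for Irf8, -0.12 to 0.0615 for Cdkn1a and -0.0699 to 0.00618 for Hoxa9. They ranged from -0.152 to 0.00288 for Mki67 in drug versus vehicle and from -0.202 to 0.0906 for Fasn in drug versus day 0. Depth can limit calls for genes with few counts. In simulated data for drug versus vehicle, 68.7% of 1.5-fold changes were recovered, and recovery was not split by count level.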

Other observations

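The gene families and the tests of the 3 patterns below were chosen after the results were seen, except the shuffles inside bins of vehicle level and the count of pairs on opposite strands. Among 14 families defined by gene symbol, Toll-like receptors, the sensors of microbial products, stood out in drug versus vehicle. All 9 tested were higher (Fisher's exact test, two-sided, adjusted p = 5.72e-06), and 8 were with library totals. The filter keeps a gene with counts in only 1 group, and a gene near 0 with vehicle can hardly be called lower. Tlr1, Tlr7 and Tlr13 reached only 2.65, 1.21 and 2.12 CPM with the drugs, after log2 rises of 3, 3.76 and 2.87. The count of 9 is thus partly built in, as for near-0 members of the other families. Tlr6 rose by 1.84 ± 0.194 and Tlr4 by 0.47 ± 0.0669 on the log2 scale, and Tlr8 averaged 6.79 CPM with the drugs against 0 counts with vehicle. The 9 were also higher than at day 0 (adjusted p = 3.19e-05 by the exact test). Of 13 C-type lectins, surface receptors of myeloid cells, 9 rose and 1 fell (exact test, adjusted p = 0.000866), with Clec4a2 higher by 2.21 ± 0.21, and 9 and 1 did so against day 0 (0.00387), while 4 had fallen in culture (0.00865; 3 with library totals, where the median turned from -0.0435 to 0.0799). Of 8 matrix metalloproteinases, 6 rose and 1 fell (adjusted p = 0.00532 by the exact test), but 4 and 1 against day 0 missed the threshold (0.229). Mmp12, the macrophage elastase, rose from 41.5 to 704.7 CPM (4.09 ± 0.122), while Mmp14, a membrane-bound collagenase, changed by -1.90 ± 0.196. Of 7 MS4A genes, 5 rose (exact test, adjusted p = 0.0154), and 6 against day 0 (0.00541).

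Of 18 myosins, 8 fell and 3 rose in drug versus vehicle (exact test, adjusted p = 0.00946), while 5 had risen and 0 fallen in culture (adjusted p = 0.00386 by the exact test; 10 and 0 with library totals). Both comparisons share the 2 vehicle libraries with opposite sign, and against day 0 the drugs gave 5 rises and 6 falls, not called in either direction (adjusted p = 0.847 and 0.498 by the exact test). The exception in size was Myo18b, which rose from 10.1 to 344.8 CPM (5.09 ± 0.121). Purinergic receptors, which sense extracellular nucleotides, had 5 rises and 1 fall among 9 and missed the threshold (exact test, adjusted p = 0.0535), as did 4 and 2 against day 0 (0.32). Their member P2rx7, the ATP-gated channel upstream of the inflammasome, rose from 0.56 to 80.6 CPM (7.12 ± 0.21).

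Rises over 2-fold outnumbered falls by 629 to 122 in drug versus vehicle. Library totals left a ratio of 4.7 (588 to 125), so the choice between TMM and library totals did not make the imbalance. They moved the median of all genes only from 0.000753 to -0.0311, too little to even out changes over 2-fold. Scaling in general was therefore not decided, and total RNA per cell was not measured. Genes averaging at least 10 CPM over all libraries gave a ratio of 5.46 (224 to 41). That mean includes the drug libraries, so a gene near 0 with vehicle could pass through a rise but not through a fall. The ratio therefore does not decide on low counts. Admixed mature neutrophils were argued against, since S100a8, S100a9, Ltf, Camp, Ngp and Retnlg together reached at most 0.0459% of Mmp8 in a drug library. Release of repressed genes under LSD1 inhibition may underlie the imbalance, a hypothesis that was not tested, because no group received that inhibitor alone.

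Neighbouring genes rose together over 2-fold in 98 adjacent pairs, against a mean of 35.1 and a maximum of 57 in 2000 shuffles of gene order (permutation p = 5e-04, the smallest they can give). Related or overlapping genes were argued against as the whole cause, since 64 pairs were left without them (shuffled maximum 49), although a rule on shared first letters misses some relatives such as Mnda and Ifi203. Clusters of genes with low vehicle levels were argued against, since shuffles inside bins of equal size by vehicle level gave a mean of 28.5 and a maximum of 49 against the same 64. Transcription running on into the next gene stays open: on opposite strands there were 25 pairs, more than the mean of 16.2 but inside the maximum of 32 (permutation p = 0.024), and the counting strand is not given. Opening of shared chromatin domains may contribute and was not tested.

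Histone genes rose between day 0 and vehicle (42 of 57) and fell with the drugs (32 of 57). Less carry-over of RNA without a poly(A) tail was argued against for the fall, since Rn45s (0.068 ± 0.197), Rmrp (0.436 ± 0.126) and Rpph1 (-0.0276 ± 0.141) all lay more than 2 SE above the histone median of -0.408 in drug versus vehicle. Of these 3 RNAs only Rmrp was called higher there (edgeR test, adjusted p = 0.019), and their synthesis was not measured. The argument therefore covers only a carry-over that the 3 RNAs share with histone transcripts. For the rise, carry-over stays open, since these RNAs differed from one another: Rn45s changed by -0.682 ± 0.198 (adjusted p = 0.054), Rmrp by 0.453 ± 0.133 (0.0562) and Rpph1 by 0.689 ± 0.149 (0.0146). More cells in S phase with vehicle also stays open for the rise, since the DNA replication list had a median of 0.0633 (adjusted p = 0.177), and that list was lower with the drugs (-0.19, adjusted p = 0.00648; 0.361 with an estimated correlation). For the rise the 2 explanations cannot be told apart here, because cell cycle phase and RNA selection were not measured separately.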
